A study of Mus musculus with 7 samples.

How the data were processed

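RNA was measured in bone marrow cells of adult FVB mice, 3 from mice labelled TRAF6 transgenic (numbers 03, 04 and 05) and 4 from wild-type littermates (21, 22, 23 and 24). Per the labels' protocols, the sort kept LSK cells, which lack mature lineage markers and carry both Sca-1 and c-Kit, a fraction rich in blood stem and progenitor cells, from mice that had received no treatment. RNA was amplified and turned into biotin-labelled sense-strand cDNA with NuGEN kits, and each mouse had 1 Affymetrix mouse exon array. The deposited log2 values were made by the authors with RMA, per the submitters' processing notes, which also name the mouse build mm9. RMA corrects background, equalises probe distributions across arrays and summarises the probes of a gene, so differences shared by most genes of an array are largely removed. Its settings, probe filters and annotation release were not given in the sources used here.

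The table held 23332 transcript clusters with 1 log2 value each per array, ranging from 1.28 to 14.03. That the scale is log2 was read from this range. Array medians ran from 5.98 (labelled transgenic 05) to 6.21 (wild type 24), and no array duplicated another. The platform annotation gave 14996 clusters 1 gene symbol, 1019 several and 7317 none, for 14860 distinct genes. Symbols were compared through Entrez identifiers with a RefSeq gene table of the later assembly GRCm38. This changed 0 symbols and left 55 single-gene clusters without a match. Because the builds differ, no coordinates are given. A gene with several clusters (135 genes) was represented by the one with the highest mean over all 7 arrays. In 56 of these genes the clusters differed in sign. Values exist for whole transcript clusters only, so exon usage, which the series design mentions, was not analysed here.

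Differences are labelled transgenic minus wild type, in log2 units. They were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, on the deposited values of all 7 arrays with genotype as the only term and no filter on low signal. P-values were adjusted by Benjamini-Hochberg over all clusters, with a threshold of 0.05. A looser count took unadjusted p under 0.05 with at least 1.5-fold difference. Traf6 was also tested by an exact permutation test over the 35 assignments of 3 among 7 arrays. P-values reflect the spread between these mice, and the number of arrays limits the precision. Replicate numbers of the groups do not overlap, so no paired fit was made.

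A total of 23 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation, with ranks, and with fry. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. List members were also counted after Benjamini-Hochberg adjustment over the list alone. The results of 1 tested list, which enters the counts of lists, are not reported here. Among the lists, 16 genes belonged to more than 1.

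Genes were named by a fixed rule. Traf6, Hnrnpa1, Arhgap1 and Cdc42 were always to be named. In each direction the rule took the 12 genes with the largest difference among those past the adjusted threshold with groups that do not overlap, filled to 12 by the smallest unadjusted p among genes with groups that do not overlap. From each list it took up to 3 members with the smallest unadjusted p. Groups, tests, lists, alternatives and this rule were fixed before the data were examined. Hnrnpa1 had no cluster of its own and was not analysed here.

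The alternatives were a low-signal filter (clusters above the 40th percentile of mean signal), quantile normalization, centring of each array on its median, array weights, an intensity trend with robust prior, a threshold of 0.1, 1 cluster per gene, unmoderated least squares, a 2-fold requirement, and leaving out each array in turn. The gene test was tried on simulated data of 23332 clusters in 3 against 4 arrays. It recovered 2 of 50 genes changed 1.5-fold, 32 of 50 changed 2-fold, 44 of 50 changed 4-fold and 48 of 50 changed 8-fold, with 2 calls among 23132 unchanged clusters. Of the simulated lists, 2 of 2 moved by 0.3 were recovered, with 0 calls among 17 unmoved lists. The simulated genes vary independently of each other, which real genes do not. Regrouping the real arrays in other ways shifted a median of 5 lists and up to 13. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.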

Results

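Transcript levels were compared between LSK cells of 3 mice labelled TRAF6 transgenic and 4 wild-type littermates. TRAF6 is a ubiquitin ligase that relays signals from Toll-like and interleukin-1 receptors to NF-kB, and the series asks how its excess acts on blood stem and progenitor cells, with RNA splicing as a possible link. The arrays resembled each other closely, with a mean pairwise Pearson correlation of 0.973 ± 0.00613 (SD, 21 pairs). Labelled transgenic pairs averaged 0.973, wild-type pairs 0.976 and pairs across the groups 0.971. Labelled transgenic 05 stood apart from the other arrays. It had the lowest mean correlation with the others (0.966), the lowest array weight (0.284) and the most extreme position (54.7) on the first principal component, which held 32.1% of the variance.

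Traf6 itself was not higher on the arrays labelled transgenic. Its level was 7.91 ± 0.34 (SD, n = 3) against 8.15 ± 0.16 (SD, n = 4), a difference of -0.24 (SE 0.18, limma adjusted p = 0.676). The 95% interval ran from -0.66 to 0.17. An exact permutation test gave p = 0.286, two-sided, with 10 of 35 assignments as large and 0.0286 the smallest p this design allows. The array therefore gave no check of the genotype label, and whether these mouse probes read the transgene was not tested. The groups are called labelled transgenic and wild type for that reason. Arhgap1, a GTPase-activating protein for Cdc42, differed by -0.19 (SE 0.15, adjusted p = 0.698) and Cdc42 by -0.15 (SE 0.13, adjusted p = 0.743), both within the spread between mice. Leaving out 1 array at a time gave -0.29 to -0.02 and -0.24 to -0.05, in both cases nearest 0 without labelled transgenic 05.

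Among clusters with a named gene, the lowest adjusted p-values belonged to a pair of Y-linked genes. Eif2s3y, a translation initiation factor gene on the Y chromosome, fell by 5.45 (SE 0.16, adjusted p = 1.82e-05), from 8.44 ± 0.27 (SD, n = 4) to 2.99 ± 0.07 (SD, n = 3). Kdm5d, a Y-linked histone demethylase gene, fell by 2.63 (SE 0.17, adjusted p = 0.00528), from 6.68 ± 0.23 (SD, n = 4) to 4.06 ± 0.26 (SD, n = 3). Both were low on all 3 arrays labelled transgenic and high on all 4 wild-type arrays. At the labelled transgenic levels 6.56% and 17.4% of clusters were lower still, and no detection call was used. Where such a level is background, the difference is a lower bound. The Y-linked signal and the labelled genotype thus coincided on 7 of 7 arrays. The labels give no sex, and no comparison here can separate genotype from this signal.

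**Figure D1:**
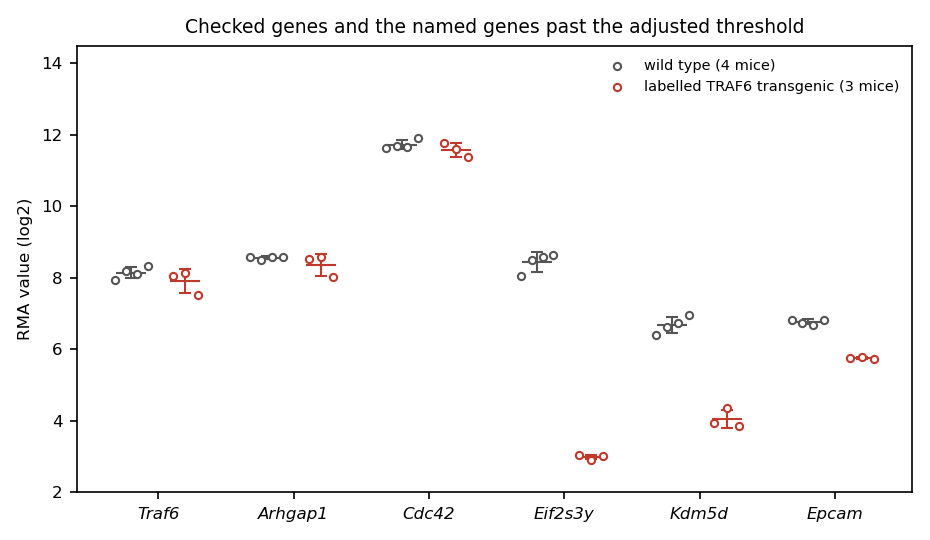
RMA values (log2, vertical axis) of the checked genes and of the named genes past the adjusted threshold, with 1 point per mouse and bars for mean and SD. Eif2s3y lies near 2.99 on the labelled transgenic arrays and 8.44 on the wild-type arrays, while the Traf6 points of the groups overlap.

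Besides the Y-linked pair, 1 named gene passed the adjusted threshold. Epcam, an epithelial cell adhesion molecule, fell by 1.01 (SE 0.09, adjusted p = 0.0399), from 6.77 ± 0.07 (SD, n = 4) to 5.76 ± 0.02 (SD, n = 3). In all, 5 transcript clusters passed, all lower, among them clusters 7023079 (-5.34, adjusted p = 1.82e-05) and 4359236 (-2.01, adjusted p = 0.00916), for which the annotation lists no gene. At the labelled transgenic level of cluster 7023079, 3.70, 13.1% of clusters were lower still, so its difference may also be a lower bound. With limma 0 clusters were higher at this threshold, against 1218 higher and 1179 lower at unadjusted p under 0.05. That is 10.3% of clusters, where chance gives 5% on average. The total of 2397 became 3668 without labelled transgenic 05 and 4726 with array weights. Unmoderated least squares called 1 cluster higher, that of Psmb10. Groups did not overlap in 2416 clusters, 10.4% against an average of 5.71% by chance. Genes do not vary independently, so a single grouping can stray from these averages. Neither share was computed for other groupings of the arrays. With the 1.5-fold requirement 770 clusters remained, 247 higher and 523 lower. Without labelled transgenic 05 this became 612 higher and 356 lower. Epcam missed the threshold on leaving out any 1 of the 7 arrays and after centring each array on its median (adjusted p from 0.0193 to 0.290 over the alternatives), and Kdm5d missed it without labelled transgenic 05 (0.0641) and with unmoderated least squares (0.109), in a range of 0.000718 to 0.109.

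The next genes by the naming rule did not pass and are given as values. Among the lower genes were Cd74, the invariant chain of class II molecules, at -1.08 (SE 0.14, adjusted p = 0.227) and H2-Ab1, a class II chain, at -0.80 (SE 0.11, adjusted p = 0.279). Emp1 differed by -1.19 and Phlda1 by -0.90 (adjusted p = 0.227 for both). With 1 cluster per gene Cd74, Emp1 and Phlda1 passed, for a cause that was not tested. Cdkn1a, the cell cycle inhibitor p21, stood at -0.80, and Dusp14, Htr7, Itgb5 and Il10ra between -0.70 and -0.80. On the higher side, F13a1, coagulation factor XIII subunit A, differed by 1.25 and Myc, a transcription factor that promotes growth, by 1.06. Mt1, a metallothionein, differed by 0.88, Rab44 by 0.81, Ctsg, the neutrophil granule protease cathepsin G, by 0.76 and Apoe by 0.65. The remaining named genes on this side were Olfr1423, Vamp5, Myh10, Ifrd2, Nsun5 and Dio2, between 0.59 and 0.73. From Cdkn1a on, these genes had adjusted p = 0.279. All the genes of this paragraph separated the 3 labelled transgenic from the 4 wild-type arrays, which the rule required. Olfr1423 (4.75 against 4.02 in wild type) and Htr7 (4.19 against 4.99) were measured at low levels, and the low-signal filter removed both.

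**Figure D2:**
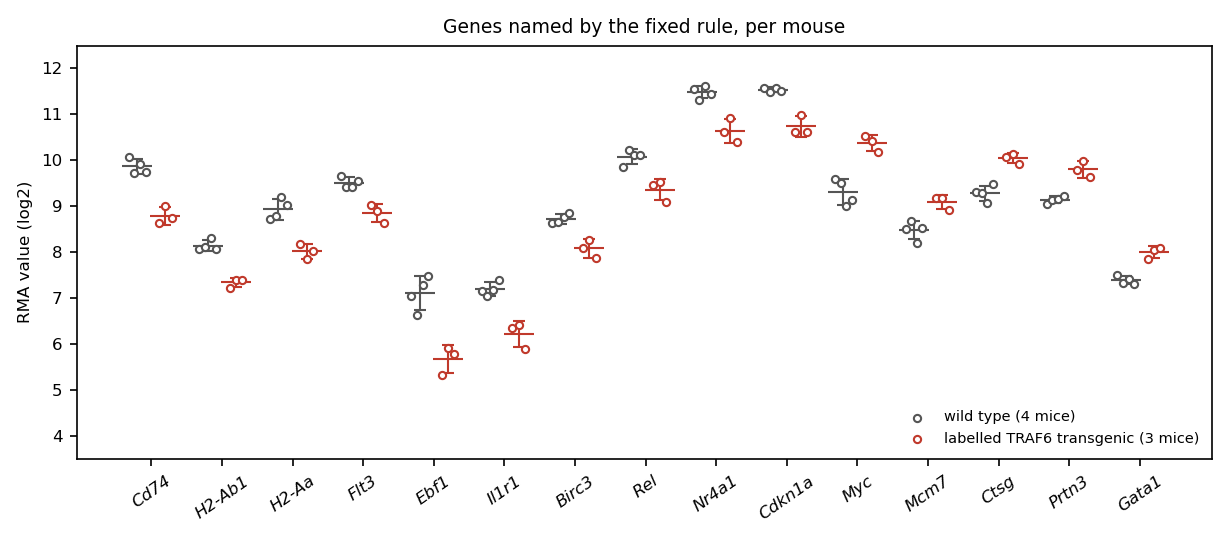
RMA values (log2, vertical axis) of genes chosen by the naming rule, with 1 point per mouse and bars for mean and SD. Cd74 lies near 8.79 on the labelled transgenic arrays and 9.87 on the wild-type arrays, and Myc near 10.4 and 9.31.

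Of the 23 lists, 15 shifted by camera at the preset correlation, 7 up and 8 down. With an estimated correlation 0 passed, the smallest adjusted p being 0.336, while 9 lists had an unadjusted fry p under 0.05 and 3 an adjusted one. No member of any tested list passed over all clusters, so the member counts given are those adjusted over the list alone. Every shift was measured along the same division of arrays as the Y-linked signal, and the array means of several lists overlapped between the groups.

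Proliferation genes shifted up furthest. Of 56 measured cell cycle genes, 52 were higher, with a median difference of 0.33 (camera adjusted p = 2.41e-13; adjusted p = 0.336 with an estimated correlation). None rose when adjusted over the list alone, and 22 were higher at unadjusted p under 0.05. Mcm7, part of the replicative helicase, was higher by 0.62 (SE 0.14), Ube2c, which serves the anaphase-promoting complex, by 0.52 (SE 0.11), and the mitotic kinesin Kif20a by 0.49 (SE 0.12). Per array, the list averaged 8.60, 8.50 and 8.26 on labelled transgenic 03, 04 and 05, and between 8.02 and 8.29 on the wild-type arrays, so the groups overlapped at array 05. Without labelled transgenic 03 the median was 0.20. Oxidative phosphorylation genes had a median of 0.12, with 37 of 50 higher (adjusted p = 0.00103; adjusted p = 0.636 with an estimated correlation). Ndufs6 and Ndufs7, subunits of respiratory complex I, were higher by 0.55 and 0.39, and Atp5j2, a subunit of ATP synthase, stood at -0.49 with groups that did not overlap. Without labelled transgenic 04 the list's median was 0.0799. This list averaged 9.44, 9.42 and 9.21 on labelled transgenic 03, 04 and 05, and 9.18 to 9.34 on the wild-type arrays, with overlap at array 05.

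Erythroid and granulocyte-monocyte progenitor genes also shifted up. Of 23 erythroid genes 21 were higher, with a median of 0.24 (adjusted p = 7.71e-05; adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone 2 rose, Apoe by 0.65 (SE 0.11) and Gata1, the main erythroid transcription factor, by 0.61 (SE 0.11). Of 23 granulocyte and monocyte progenitor genes 18 were higher, with a median of 0.15 (adjusted p = 0.0154; adjusted p = 0.600 with an estimated correlation). Adjusted over the list alone 4 rose and 1 fell. Those that rose included the granule proteases Ctsg (0.76, SE 0.13) and Prtn3 (0.66, SE 0.12) and the receptor gene Trem3 (0.65, SE 0.14). The 1 that fell was Clec12a (-0.64, SE 0.15). Trem3 was measured at a low level, 4.62 against 3.98 in wild type, and the low-signal filter removed it. The progenitor list missed the threshold once low-signal clusters were left out (0.0784; range 0.00927 to 0.600). Without wild type 22 its median was 0.0955, and that of the erythroid list without labelled transgenic 04 was 0.38. Array means of both lists overlapped between the groups. On labelled transgenic 03, 04 and 05 the erythroid list averaged 7.20, 6.97 and 7.29, against 6.73 to 7.05 in wild type. The progenitor list averaged 8.10, 8.14 and 7.95, against 7.88 to 8.03.

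Genes of multipotent and lymphoid-primed progenitors shifted down, with 19 of 25 lower and a median of -0.27 (adjusted p = 0.000147; adjusted p = 0.336 with an estimated correlation). Over the list alone 2 fell, Flt3, a cytokine receptor of early lymphoid progenitors, by 0.67 (SE 0.13) and Gimap6 by 0.87 (SE 0.17). Satb1 was lower, at -0.44 (SE 0.12). The median was -0.149 without labelled transgenic 05 and -0.142 with array weights. B cell markers had a median of -0.13, with 10 of 15 lower (adjusted p = 0.00762; adjusted p = 0.336 with an estimated correlation). Over the list alone 5 fell, among them Ebf1 (-1.43, SE 0.23) and Pax5 (-0.66, SE 0.14), transcription factors of B cell commitment, and Cd37 (-0.47, SE 0.12). T and NK cell markers had a median of -0.10, with 18 of 22 lower (adjusted p = 0.00442; adjusted p = 0.336 with an estimated correlation), and Cd28, a costimulatory receptor, fell by 1.08 (SE 0.20) over the list alone. Macrophage and dendritic cell markers had a median of -0.08, with 16 of 28 lower (adjusted p = 0.00795; adjusted p = 0.336 with an estimated correlation). The 4 that fell over the list alone were the class II genes Cd74, H2-Ab1 and H2-Aa (-0.92, SE 0.15) and Flt3, none of which is specific to macrophages. The B, T and NK, and macrophage and dendritic lists were the 3 with an adjusted fry p under 0.05 (0.0464 each). Without labelled transgenic 03 they missed the camera threshold, at 0.0854, 0.0688 and 0.0602, and the last also missed it without wild type 21 (0.0825). Over the alternatives their adjusted p ranged from 0.00163, 0.00144 and 0.000163 to 0.336. All 3 medians moved with the scaling, and 2 of them with the low-signal filter. Without low-signal clusters the B cell median was -0.446 and the macrophage and dendritic median -0.427. Quantile normalization gave -0.0648, -0.0389 and -0.0363 for the B, T and NK, and macrophage and dendritic lists, and centring -0.0719, -0.0450 and -0.0255. The B cell median was -0.0488 without labelled transgenic 03, -0.230 without 05 and -0.0364 without wild type 23, and the macrophage and dendritic median -0.0386 without wild type 21.

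NF-kB target genes were lower, with 29 of 41 below the wild-type level and a median of -0.17 (adjusted p = 7.71e-05; adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone 11 fell and 1 rose. Those that fell included Birc3, an inhibitor of apoptosis (-0.65, SE 0.13), the stress-response gene Gadd45b (-0.88, SE 0.18) and Rel, an NF-kB subunit (-0.72, SE 0.15). The list averaged 7.19, 7.22 and 6.98 on labelled transgenic 03, 04 and 05, and between 7.31 and 7.44 on the wild-type arrays. Its median was -0.298 without low-signal clusters and -0.109 after centring. Immediate early and heat shock genes had a median of -0.11, with 22 of 34 lower (adjusted p = 0.00819; adjusted p = 0.637 with an estimated correlation). Over the list alone 8 fell, including the nuclear receptor gene Nr4a1 (-0.83, SE 0.15) and Gadd45a (-0.60, SE 0.12), and Myc rose by 1.06 (SE 0.18). This list shares 2 genes with the NF-kB list. Components of Toll-like receptor, IL-1 receptor and TRAF6 signalling had a median of -0.09, with 28 of 40 lower (adjusted p = 0.0240; adjusted p = 0.637 with an estimated correlation). Over the list alone the interleukin-1 receptor gene Il1r1 fell by 0.97 (SE 0.16) and Tifab rose by 0.45 (SE 0.09). The signalling list averaged 6.87, 6.78 and 6.54 on labelled transgenic 03, 04 and 05, against 6.78 to 7.01 on the wild-type arrays. Its median was -0.0225 without labelled transgenic 05, -0.0596 without wild type 24 and -0.0350 after centring. The immediate early median was -0.0393 and -0.198 without labelled transgenic 05 and 04, -0.0556 and -0.245 without wild type 21 and 24, -0.0547 after centring and -0.0697 with array weights. Without labelled transgenic 05 the immediate early list stood at 0.0559 and the signalling list at 0.399, and without wild type 21 at 0.202 and 0.0698. The immediate early list also missed the threshold without wild type 22 (0.0589) and the signalling list without wild type 24 (0.0673), in ranges of 4.22e-05 to 0.637 and 0.00754 to 0.637 over the alternatives.

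Interferon and class I genes shifted the other way. Type I interferon response genes had a median of 0.21, with 24 of 29 higher (adjusted p = 0.000261; adjusted p = 0.336 with an estimated correlation). None passed when adjusted over the list alone. Rtp4 was higher by 0.70 (SE 0.17) and Irgm1, an interferon-inducible GTPase, by 0.55 (SE 0.17), while Samd9l stood at -0.65 (SE 0.18). Without labelled transgenic 03 the median was 0.125. The list averaged 7.10, 7.00 and 6.88 on labelled transgenic 03, 04 and 05, and 6.74 to 7.03 on the wild-type arrays, so the groups overlapped. MHC class I and antigen processing genes had a median of 0.19, with 11 of 12 higher (adjusted p = 0.00197; adjusted p = 0.336 with an estimated correlation). The immunoproteasome subunit gene Psmb10 rose by 0.38 (SE 0.09) over the list alone, and the related subunits Psmb9 and Psmb8 were higher by 0.30 and 0.29. The class I list averaged 10.09, 10.07 and 9.89 on labelled transgenic 03, 04 and 05, and 9.80 to 9.93 on the wild-type arrays, with overlap at array 05.

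Of the splicing lists, which bear on the question of the series, the core spliceosome list passed at the preset correlation (adjusted p = 0.696 with an estimated correlation) and the regulator list did not. Splicing regulators of the hnRNP and SR families had a median of 0.00342, with 20 higher and 20 lower (adjusted p = 0.549). Srsf1 was higher by 0.33 (SE 0.13) and Elavl1 by 0.29 (SE 0.12), and Ptbp2 stood at -0.43 (SE 0.22). Without labelled transgenic 05 the median was 0.117 and the list passed the threshold (0.0484; range 0.0484 to 0.970). Core spliceosome and splice site recognition genes had a median of 0.08, with 31 of 44 higher (adjusted p = 0.00773; adjusted p = 0.696 with an estimated correlation), Prpf31 being higher by 0.43 (SE 0.14) and Sf3b3 by 0.37 (SE 0.12). The list averaged 9.38, 9.35 and 9.07 on labelled transgenic 03, 04 and 05, against 9.07 to 9.27 on the wild-type arrays. Labelled transgenic 05 was level with the lowest of these, wild type 21. No gene of either list passed when adjusted over the list alone. The spliceosome list missed the threshold without labelled transgenic 03, without 04 and without wild type 21 (0.0854, 0.0554 and 0.0738; range 0.000173 to 0.696). Its median was 0.0275, 0.0479 and 0.187 without labelled transgenic 03, 04 and 05, 0.137 after centring and 0.165 with array weights.

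Long-term stem cell genes did not pass, with 21 of 35 lower and a median of -0.08 (adjusted p = 0.193). Gfi1b was higher by 0.57 (SE 0.13), while Hlf stood at -0.57 (SE 0.19) and Hoxb4 at -0.33 (SE 0.12). Without labelled transgenic 05 the median was 0.123 and without 04 it was -0.15, where the list passed (0.0158; range 0.0158 to 0.816).

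**Figure D3:**
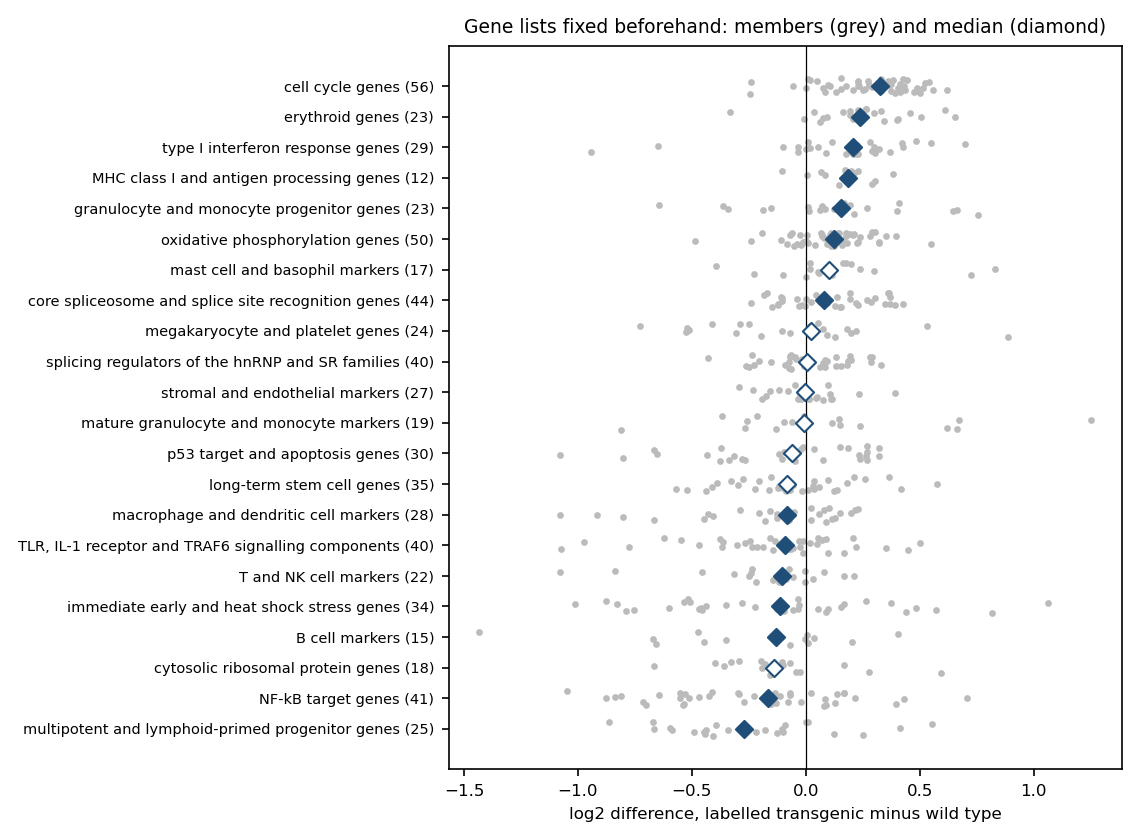
Log2 difference, labelled transgenic minus wild type (horizontal axis), for the members (grey points) and median (diamond) of each list, with measured members in parentheses and filled diamonds for lists past the camera threshold at the preset correlation; 1 tested list is not drawn. Cell cycle genes have the highest median, 0.33, and multipotent and lymphoid-primed progenitor genes the lowest, -0.27.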

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

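The tests of handling stress, mature B cells, dendritic cells and sex of the mice for the gene list shifts were chosen after those shifts had been seen, and the bound on X-linked genes after the Y-linked values but before the X-linked ones. Further requirements were added after the values of the sets were seen. A marker set had to hold at least 3 members above the low-signal percentile to decide anything. To exclude an explanation, it also had to pass its bound by more than its spread. The spread of a set is the standard error of the group difference in its per-array means. By the bounds alone, handling stress, B cells and dendritic cells would each have been excluded.

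Low Y-linked signal on all 3 arrays labelled transgenic may reflect female mice set against male ones. The test was whether genes that escape X inactivation were higher there. Their median difference was 0.22 over 4 genes, 3 of them higher, with Kdm5c at 0.41 (SE 0.14), Eif2s3x at 0.39 (SE 0.13), Kdm6a at 0.06 (SE 0.15) and Ddx3x at -0.10 (SE 0.11). An exact permutation test gave p = 0.114, with 4 of 35 assignments as large, and the set's spread was 0.12. The median met the bound of 0.2 set for female against male mice, though by less than that spread. Loss of Y-linked expression in mice of the same sex is therefore not excluded by this test.

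The NF-kB and immediate early lists had medians of -0.17 and -0.11 on the arrays labelled transgenic, past the threshold at the preset correlation (adjusted p = 0.336 and 0.637 with an estimated correlation). The immediate early list averaged 9.18, 9.25 and 8.88 there, within or below the 9.01 to 9.44 of wild type, and 12 of its 34 genes were higher. Less handling stress of those cells is a candidate explanation. The 16 handling genes tested are all members of the 34-gene immediate early list, so they are no independent test of it. Their median was 0.0283, with 8 higher and 8 lower, from -0.52 (Dnajb1) to 0.82 (Fos). The SD between these genes was 0.38, and the spread of the set, as defined above, was 0.20. The other 18 members had a median of -0.45, with 14 lower. The explanation stays open. Sex of the mice cannot be told apart from labelled genotype, since Y-linked signal and genotype coincide on 7 of 7 arrays. A genotype effect stays open and untested for the same reason.

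The class II genes Cd74, H2-Ab1 and H2-Aa and members of the lymphoid-primed and B cell lists were lower; whether they moved together was not tested, and both lists had adjusted p = 0.336 with an estimated correlation. Fewer mature B cells in the sorted fraction could lower Cd74 and Pax5, but 8 mature B cell genes had a median difference of 0.00753 at a mean level of 4.92 against 4.90. Of these, 2 lay above the low-signal percentile, Cd79b being the most abundant (8.05 against 7.65). Dendritic cells could lower class II genes too. There 4 genes had a median of -0.0148, with 0 above the percentile and Siglech the most abundant (5.27 against 5.33), and the lineage depletion of the sort would remove most mature cells. Marker sets this close to the floor decide nothing, and sex again coincides with genotype on 7 of 7 arrays.

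Dixon's test was applied to 114 items on the 4 wild-type arrays, namely gene levels, list means and array summaries. In 3 of them, all gene levels, 1 array lay far from the rest, which is fewer than the 1 in 20 that chance gives. Arhgap1 was 8.50 in wild type 22, the nearest other array being at 8.58. Elavl1 was 9.35 in wild type 24, against 9.25 on the nearest other. Ndufs7 was 9.13 in wild type 23, against 9.47.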

How the results depend on the processing

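Over the planned settings no named gene changed sign and Traf6 stayed short of the threshold, between -0.36 and -0.05. Over the leave-outs Ptbp2 ran from -0.58 to -0.26 and Hlf from -0.71 to -0.32. The cause of the changes listed here was not tested. The clusters past the adjusted threshold numbered 4 after median centring and with least squares, 6 with 1 cluster per gene, and 2 to 4 when 1 array was left out. Eif2s3y and cluster 7023079 passed in every leave-out. Cluster 4359236 missed the threshold without labelled transgenic 04 or 05, without wild type 21, 22 or 24, and with least squares (0.109). The 2397 clusters at unadjusted p under 0.05 became 4726 with weights and 1618 to 3668 over the leave-outs. The looser count of 770 was 500 without low-signal clusters, 1212 with array weights, 200 at 2-fold, 491 with least squares, 297 with 1 cluster per gene, and 710 to 1094 over the leave-outs. Its higher share, 32.1%, was 47.7% after centring, 49.4% with weights and 63.2% without labelled transgenic 05. Of all 23 lists, 15 shifted, against 0 with an estimated correlation, 3 with fry, and 10 to 18 over the leave-outs, the most without labelled transgenic 04. NF-kB, interferon, multipotent progenitor, erythroid, cell cycle, class I and oxidative phosphorylation lists lost their call only with an estimated correlation and fry. The receptor signalling list also lost it without low-signal clusters (0.0830) and with array weights (0.223), the immediate early list with weights (0.105) and ranks (0.0596), and the B cell and macrophage lists with ranks (0.0538 and 0.0834). Genes past the threshold over their list alone numbered 46, against 81 with quantile normalization, 78 with centring, 101 with weights, and 23 to 69 over the leave-outs, the lowest without wild type 23. The mean correlation between arrays was 0.958 without low-signal clusters.

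Lists that had not passed changed direction under some settings. Long-term stem cell genes had a median of 0.0978 with array weights and -0.172 to 0.123 over the leave-outs. Stromal and endothelial markers had 0.0216 with quantile normalization, 0.0545 with centring and -0.0296 to 0.0307 over the leave-outs. The leave-outs gave -0.0429 to 0.0410 for mature granulocyte markers, -0.0965 to 0.0715 for megakaryocyte genes and -0.0507 to 0.117 for hnRNP and SR regulators. The median of p53 targets turned to 0.0787 without labelled transgenic 05 and 0.0606 with array weights. No paired analysis was made, because the groups share no replicate numbers. The sample fields used here name no litter, so any litter shared between the groups could not be modelled. With 3 and 4 arrays, the simulation recovered 2 of 50 genes changed 1.5-fold, so smaller differences were seldom detectable.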

Other observations

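Some lists that did not pass hold members that moved. Mature granulocyte and monocyte markers had a median of -0.00796, a mean of 0.09 and an upward test (adjusted p = 0.458). Adjusted over the list alone 3 rose, F13a1 by 1.25, the chemokine receptor gene Cxcr2 by 0.67 and Ms4a6c by 0.62. Without low-signal clusters the list passed, with a median of 0.38 (adjusted p = 0.0221; range 0.0221 to 0.983). P53 target and apoptosis genes had a median of -0.06, with 18 of 30 lower (adjusted p = 0.191), and the median was 0.0787 without labelled transgenic 05. Over the list alone Cdkn1a fell by 0.80 and Perp by 1.08. Mast cell and basophil markers had a median of 0.10, with 14 of 17 higher (adjusted p = 0.0536), with a median of 0.0516 without wild type 22 and 0.0282 without low-signal clusters, and Gzmb, granzyme B, rose by 0.83 over the list alone.

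Megakaryocyte and platelet genes had a median of 0.02, a mean of -0.06 and a downward test (adjusted p = 0.191). The platelet genes Pf4 and Plek stood at -0.52 and -0.51, and Selp, P-selectin, was higher by 0.89. Without labelled transgenic 04 the megakaryocyte, p53 and mast cell lists passed (0.0160, 0.0307 and 0.0257). Stromal and endothelial markers (median -0.00328, adjusted p = 0.827) and cytosolic ribosomal protein genes (median -0.14, 15 of 18 lower, adjusted p = 0.0970) did not pass. The ribosomal median ran from -0.155 to -0.0308 over the leave-outs, nearest 0 without labelled transgenic 05.

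Splitting the 7 arrays in all 35 ways into 3 and 4 showed how often a grouping gives counts as large. The labelled split is 1 of the 35 and enters each number of splits given here. For clusters past the adjusted threshold, 2 of 35 splits gave 5 or more, the highest other being 6. Chance is therefore not excluded for this count. The count does not weigh which clusters passed or by how much. Eif2s3y (-5.45) and cluster 7023079 (-5.34), each with limma adjusted p = 1.82e-05, passed in every leave-out. For the looser count, 3 of 35 splits gave 770 or more, the highest other being 1078, and chance is not excluded for this count either. Both highest splits set labelled transgenic 04 and 05 and wild type 21 against the rest. For shifted lists, 1 of 35 splits, the labelled one, reached 15, the highest other being 13. The other splits had a median of 5. The labelled split thus ranked first for this count, at the preset correlation only. A first rank is the smallest share that 35 splits allow, and several counts were put to this test. The splits therefore do not decide whether chance gave this count. With an estimated correlation 0 lists passed, leaving out 1 array gave 10 to 18, and genotype and sex are not separated by the splits.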
